A study of Mus musculus with 9 samples.

How the data were processed

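RNA-seq of mouse heart was compared between 3 groups of 3 libraries: WT mice given saline, WT mice given doxorubicin and Sting-/- mice given doxorubicin. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a QIAGEN kit and libraries were made with an MGI kit.

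The authors deposited 1 file per library with a gene ID and an FPKM value printed to 2 decimals, for the same 16873 genes in each file. Per the submitters' processing notes, the tools named are HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 and the genome build is GRCm39, with no role or order given. FPKM is relative to each library's own total, so a few abundant genes can shift all others, and it keeps no read counts, so no count model was used. Values summed to 552456 to 555425 FPKM in the saline libraries, 559998 to 570128 in WT DOX and 539287 to 543352 in Sting-/- DOX. The 10 most abundant genes held 16.6%, 11.8% and 8.28% of these sums on average. No mitochondrially encoded gene was among the genes analysed here, so that list could not be tested.

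Gene IDs were matched to symbols through a RefSeq gene table of the GRCm38.p6 assembly, used for names and gene neighbourhood only because the files use another build, so no coordinates are printed. Of the IDs, 16825 matched and 48 did not. Depth was estimated from low values of 1994 genes with a single transcript, whose values step by what 1 read is worth. The steps fitted better than shuffled values did but were not exact, with 49.4% to 59.3% of values within 0.1 reads of a whole number, so the depth is approximate and no counts were recovered.

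Values were tested as log2(FPKM + 1) with limma 3.58.1 (trended variance prior, all 9 libraries in 1 fit with 6 residual degrees of freedom) in R 4.3.3, on the 12485 genes with a mean of at least 1 FPKM over all libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 3 against 3 cannot go below p = 0.1. Gene lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. Of 42 lists fixed before the data were examined, covering pathways, technical signs and cell types, 41 had at least 3 tested members. Some lists share members and are not separate evidence. Among them are the sarcomere and cardiomyocyte lists, the inflammatory and neutrophil lists, and the lists of oxidative phosphorylation and the tricarboxylic acid cycle. Counts of members adjusted over the list alone equalled those over all genes wherever no other count is given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, permutation tests and figures.

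The rule for naming genes was fixed before the data were examined. It takes a panel of 21 genes, the 8 largest rises and 8 largest falls of each comparison whose group ranges do not overlap, predicted genes left out, up to 4 members of each list that passed and up to 2 that went the other way, at most 2 members of other lists, and the 8 genes with the largest opposite changes. Genes named outside the rule are said to be so. Fold changes of genes at a mean near 0 are understated on this scale.

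The limma and camera steps were tested on simulated data with 100 genes changed by each of the sizes tried. Of genes changed by 0.5 and 1 on the log2 scale, 79% and 98% were recovered in WT DOX against saline (12352 genes), 81% and 99% in Sting-/- DOX against WT DOX (12381 genes), and 96% and 99% in Sting-/- DOX against saline (12363 genes). Among the unchanged genes of these simulations, 3, 5 and 12 were called. With nothing changed, no gene and no list was called. The simulated genes varied independently, so this does not test camera on lists whose members vary together. In the data the estimated correlation was as high as 0.747, for the interferon-stimulated genes. Alternatives covered the pseudocount, the filter on low values, the scaling, the samples in the fit, the variance prior, sample weights, a replicate block, the correlation in camera and leaving out each library. Counts of genes changed by at least 2-fold were added after the data were seen. Tests of a pattern among clock genes, made after the data were seen, are not reported here.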

Results

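RNA was sequenced from the hearts of wild-type (WT) mice given saline, WT mice given doxorubicin (DOX) and mice lacking Sting given doxorubicin, with 3 libraries in each of the 3 groups. Doxorubicin is an anthracycline cancer drug that can injure the heart. STING is the adaptor through which the DNA sensor cGAS switches on interferon and inflammatory genes. The series asks what this pathway does to the doxorubicin-treated heart, its endothelial cells and their NAD metabolism. The files gave the expression of 16873 genes as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), of which 12485 had a mean of at least 1 FPKM and were tested. Read totals were not given, and the whole-read steps of low values put the depth, in units of 1e+06 fragments, at about 10.7 to 11.7 in the saline libraries, 13.0 to 13.4 in the WT DOX libraries and 8.1 to 8.4 in the Sting-/- DOX libraries. No library of untreated Sting-/- hearts was analysed here, so an effect of the genotype without the drug is part of every comparison with the Sting-/- group. The effect of the genotype on the response to doxorubicin could not be tested as an interaction. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

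The libraries of each group lay close together and the groups lay far apart. Pearson's r across genes was 0.9948 to 0.9968 between libraries of the same group, 0.936 to 0.943 between saline and WT DOX, 0.848 to 0.852 between WT DOX and Sting-/- DOX, and 0.770 to 0.777 between saline and Sting-/- DOX. Genes are not independent replicates, and these values describe the libraries. The first principal component held 81.6% of the variance and the second 15.8%.

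**Figure D1:**
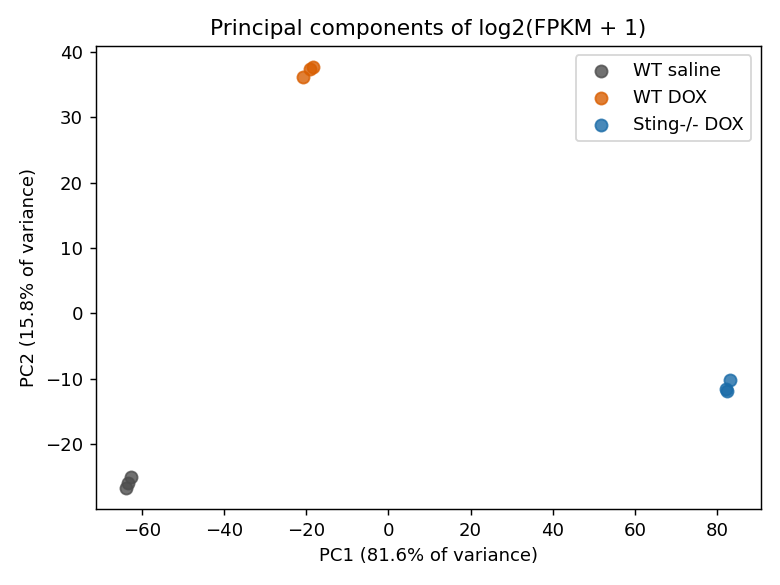
Each point is 1 library, placed by its scores on the first principal component (x axis, 81.6% of the variance) and the second (y axis, 15.8%) of log2(FPKM + 1), with 3 libraries per group. The 3 libraries of each group overlap or nearly overlap, and the Sting-/- DOX libraries lie farther from the saline libraries on the first component than the WT DOX libraries do.

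Sting1 (gene ID 72512), the deleted gene, was at 5.49 ± 0.418 FPKM in saline hearts and 17.7 ± 0.236 FPKM in WT DOX hearts (SD, n = 3 each). In the Sting-/- libraries it was at 0.06, 0 and 0 FPKM. The libraries labelled Sting-/- therefore differed from the WT libraries in the gene named by their label.

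The first comparison asked what doxorubicin changed in WT hearts. Genes of cardiac stress, matrix, inflammation and interferon response rose, and genes of mitochondrial metabolism and contraction fell. With an estimated correlation in camera, the lists of cardiac stress, matrix, interferon response, oxidative phosphorylation, fatty acid oxidation and contraction no longer passed. Of the 12485 genes tested, 5651 were higher and 2680 lower in WT DOX than in saline (limma, adjusted p of 0.05), and 1160 and 85 of these changed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. The ranges of both groups did not overlap for 8947 genes (71.7%), where chance gives 10%. The largest rises were those of Spp1, which encodes osteopontin, from 1.38 ± 0.300 to 571.6 ± 14.0 FPKM (SD, n = 3 each; log2 fold change 7.92, SE 0.076, limma adjusted p = 3.09e-14), Arg1 (7.09), Sprr1a (6.86), Timp1 (6.36), Chil3 (5.37), S100a8 (5.30), Plac8 (5.12) and S100a9 (5.02). The largest falls were those of Nr4a1 (-2.43), Inmt (-2.37), Nnt (-2.0), Retnla (-1.98), Ces1d (-1.87), Scn4b (-1.76), Hspa1a (-1.66) and Lgi1 (-1.48).

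The fixed list of cardiac stress genes rose in WT DOX, with 9 of 13 members higher and 3 lower and a median log2 fold change of 1.51 (camera adjusted p = 0.0109; adjusted p = 0.288 with an estimated correlation). The atrial cardiomyocyte markers, which share Nppa and Myl4 with it, had 5 of 8 higher and 3 lower and a median of 1.73, and did not pass the test (camera adjusted p = 0.466). Nppa, which encodes atrial natriuretic peptide, went from 202.9 ± 18.3 to 2798 ± 174 FPKM, and Nppb, which encodes brain natriuretic peptide, from 230.2 ± 21.4 to 1277 ± 35.4 FPKM (SD, n = 3 each). Myh7, the beta myosin heavy chain, rose from 34.6 ± 0.962 to 123.7 ± 25.2 FPKM (limma adjusted p = 3.58e-08), while Nfatc2 fell by 0.35 on the log2 scale. Actc1 fell by 0.36, and was 0.13 higher, not lower, with quantile normalization. Matrix genes rose in 25 of 27 cases, with a median of 1.91 (camera adjusted p = 8.89e-11; adjusted p = 0.103 with an estimated correlation). Col1a1 went from 15.6 ± 0.516 to 126.0 ± 0.942 FPKM, and Mmp2 fell by 0.18 on the log2 scale. The fibroblast markers as a list did not pass the test, with 8 of 14 higher (9 adjusted over the list alone), 4 lower and a median of 0.23 (camera adjusted p = 0.489).

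Inflammatory cytokines and adhesion molecules were higher in all 22 tested cases, with a median log2 fold change of 2.35 (camera adjusted p = 5.9e-09; adjusted p = 0.0191 with an estimated correlation). Ccl2, a monocyte chemoattractant, went from 4.55 ± 0.823 to 131.6 ± 12.3 FPKM, Lcn2 from 2.33 ± 0.367 to 74.4 ± 7.01 FPKM and Vcam1 from 7.24 ± 0.552 to 15.7 ± 0.930 FPKM (SD, n = 3 each). The neutrophil markers rose in 7 of 7 cases (median 3.26, camera adjusted p = 6.84e-05; adjusted p = 0.083 with an estimated correlation). The macrophage and monocyte markers rose in 16 of 19 cases (median 1.39, camera adjusted p = 5.58e-06; adjusted p = 0.0557 with an estimated correlation). Lgals3, Ccr2 and Cd68 were among them, while Cd163 fell by 0.48 on the log2 scale. MHC class II genes rose in 8 of 8 cases and T and natural killer cell markers in 9 of 10 (camera adjusted p = 0.0178 and 0.0247; adjusted p = 0.375 and 0.43 with an estimated correlation).

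Interferon-stimulated genes were higher in 35 of 36 tested cases, with a median log2 fold change of 1.08 (camera adjusted p = 6.84e-05; adjusted p = 0.49 with an estimated correlation, which was 0.747). Isg15 went from 32.1 ± 7.08 to 90.9 ± 22.6 FPKM and Cxcl10, which encodes a chemokine that draws T cells, from 3.52 ± 0.920 to 16.4 ± 2.0 FPKM. Spread between the WT DOX libraries was wide for some members, and Ifit3 was at 81.3, 168.7 and 124.4 FPKM in them (limma adjusted p = 0.000146), a value that is uncertain because Ifit3b is a near-identical copy. The cGAS-STING list rose in 15 of 16 cases (median 0.85, camera adjusted p = 9.0e-04; adjusted p = 0.103 with an estimated correlation). Cgas (gene ID 214763) was at 0.693 ± 0.219 FPKM in saline and 2.30 ± 0.108 FPKM in WT DOX, and Irf7, the interferon regulatory factor, went from 88.4 ± 3.42 to 214.3 ± 28.6 FPKM (SD, n = 3 each). Mavs fell by 0.25 on the log2 scale. Tbk1 rose by 0.27 and Irf3 by 0.21, calls that were lost with median-ratio scaling at 0.041 and -0.035 and with quantile normalization at 0.041 and 0.022. MHC class I genes, whose H2 members share sequence and are uncertain one by one, rose in 11 of 11 cases (median 0.92, camera adjusted p = 9.46e-04; adjusted p = 0.196 with an estimated correlation).

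Nuclear genes of mitochondrial metabolism fell by modest amounts. The tricarboxylic acid cycle list was lower in 18 of 18 cases (median -0.49, camera adjusted p = 3.99e-13; adjusted p = 0.0191 with an estimated correlation). The oxidative phosphorylation list was lower in 47 of 51 (49 adjusted over the list alone; median -0.40, camera adjusted p = 2.42e-21; adjusted p = 0.079 with an estimated correlation). Fatty acid oxidation genes were lower in 27 of 30 (median -0.52, camera adjusted p = 5.28e-14; adjusted p = 0.083 with an estimated correlation), and Cpt1a rose by 0.29 on the log2 scale, a call lost with median-ratio scaling (0.045) and quantile normalization (0.087). The list of mitochondrial biogenesis and dynamics fell in 16 of 24 cases (17 adjusted over the list alone), Ppargc1a among them, from 25.5 ± 0.186 to 16.1 ± 0.698 FPKM (camera adjusted p = 4.46e-05; adjusted p = 0.0381 with an estimated correlation). Beside these falls, the cardiomyocyte markers fell in 13 of 16 cases, with a median of -0.58 (camera adjusted p = 5.92e-09; adjusted p = 0.0467 with an estimated correlation), including Mb, Ckm and Pln. Nkx2-5, a cardiac transcription factor, rose by 0.16 on the log2 scale (limma adjusted p = 0.0489), but was at -0.091 with median-ratio scaling and -0.028 with quantile normalization. The call was also lost with a lower pseudocount, no filter on low values, no variance trend or TPM scaling with or without haemoglobin genes, and without saline library 1 or 2, WT DOX library 1 or 3 or Sting-/- DOX library 2 (0.10 to 0.18). Sarcomere genes fell in 13 of 18 cases (median -0.41, camera adjusted p = 1.13e-05; adjusted p = 0.083 with an estimated correlation), a call lost with quantile normalization (mean -0.16 against -0.28), and genes of calcium handling in 11 of 18 (camera adjusted p = 0.0013; adjusted p = 0.213 with an estimated correlation). The glycolysis list did not pass the test, with 10 of 20 higher and 8 lower (11 and 9 adjusted over the list alone; camera adjusted p = 0.827).

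Among genes of NAD metabolism, neither fixed list passed the test: NAD consumption had a median log2 fold change of 0.41 (camera adjusted p = 0.401) and NAD synthesis one of -0.10, with a mean of 0.28 (camera adjusted p = 0.232). Of these lists, 12 of 18 and 3 of 15 members were higher and 3 and 6 lower. Single members changed by large amounts. Nmrk2 (gene ID 69564), which encodes a kinase that makes nicotinamide mononucleotide, a precursor of NAD, from nicotinamide riboside, went from 10.1 ± 0.493 to 289.2 ± 40.0 FPKM (log2 fold change 4.71, SE 0.081, limma adjusted p = 1.12e-12). Bst1 (gene ID 12182), the paralog of Cd38, rose from 1.05 ± 0.296 to 9.22 ± 0.329 FPKM, and Cd38 (gene ID 12494), which breaks down NAD, rose from 6.32 ± 0.497 to 8.74 ± 0.386 FPKM (log2 fold change 0.41, SE 0.062, limma adjusted p = 9.21e-05). Nnt (gene ID 18115), the mitochondrial NAD(P) transhydrogenase, fell from 316.5 ± 15.2 to 78.5 ± 2.71 FPKM. Nampt, which encodes the rate-limiting enzyme of NAD salvage, had a log2 fold change of -0.20 (limma adjusted p = 0.0554), which passed the test without WT DOX library 2 (-0.33), with median-ratio scaling (-0.45) and with quantile normalization (-0.38). It also passed with a mean of at least 5 FPKM, sample weights and TPM scaling with or without haemoglobin genes (-0.20 to -0.24). Parp1 had one of 0.13 (limma adjusted p = 0.048), which was at -0.11 with median-ratio scaling and -0.065 with quantile normalization. The call was also lost with no filter on low values, TPM scaling with or without haemoglobin genes, only the 2 groups compared, no variance trend, sample weights or a replicate block. It was lost as well without saline library 1 or 2, WT DOX library 1 or 2 or Sting-/- DOX library 2 or 3, and all these settings gave 0.094 to 0.14.

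**Figure D2:**
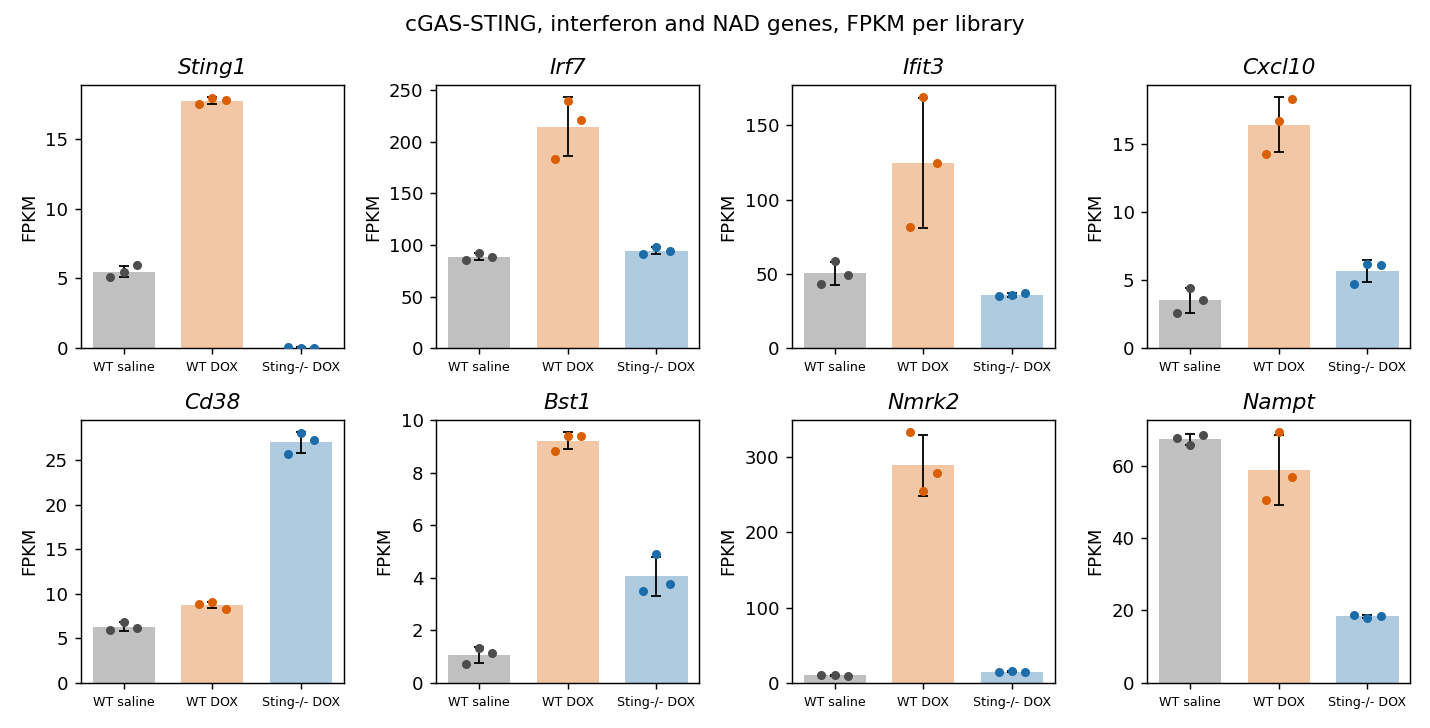
Bars are group means of FPKM (y axis), error bars are SD, and points are the 3 libraries of each group for 8 genes of the cGAS-STING, interferon and NAD lists. Irf7, Ifit3, Cxcl10, Bst1 and Nmrk2 are highest in WT DOX, while Cd38 is highest in Sting-/- DOX, at 27.0 FPKM.

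Several other lists rose in WT DOX. Cell cycle genes were higher in 27 of 28 cases (median 1.44, camera adjusted p = 4.61e-08; adjusted p = 0.0419 with an estimated correlation), and senescence-associated genes in 12 of 12 (median 2.18, camera adjusted p = 2.86e-05; adjusted p = 0.0381 with an estimated correlation). Cdkn1a, the p21 cell cycle inhibitor, went from 11.8 ± 1.63 to 53.6 ± 4.72 FPKM, although the list of p53 targets did not pass the test (median 0.24, camera adjusted p = 0.438). The integrated stress response list rose in 16 of 19 cases (median 0.81, camera adjusted p = 9.46e-04; adjusted p = 0.079 with an estimated correlation). Ribosomal protein genes rose in 26 of 26 cases, with a median of 0.78 (camera adjusted p = 2.23e-10; adjusted p = 0.0381 with an estimated correlation). The circadian clock list fell in 11 of 17 cases (median -0.54, camera adjusted p = 2.73e-04; adjusted p = 0.129 with an estimated correlation), the erythroid list in 7 of 8 (camera adjusted p = 6.84e-05; adjusted p = 0.123 with an estimated correlation) and smooth muscle markers in 7 of 13 (camera adjusted p = 0.0089; adjusted p = 0.212 with an estimated correlation). The endothelial markers, with 7 of 23 higher and 7 lower, had a median of 0.03 and did not pass the test (camera adjusted p = 0.233), whereas with median-ratio scaling their mean was -0.18 and they passed as lower. In all, 24 of the 41 lists tested passed, and 7 passed with an estimated correlation.

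How many genes count as higher or lower depended on the scaling between samples. Of the genes called, 67.8% were higher in WT DOX with FPKM as deposited, 41.2% with median-ratio scaling and 39.2% with quantile normalization. The median log2 fold change of all genes tested moved from 0.128 to -0.085 with median-ratio scaling and -0.104 with quantile normalization. Relative to the median of all genes, the list medians were -0.62 for the tricarboxylic acid cycle, -0.70 for cardiomyocyte markers, 0.95 for interferon-stimulated genes and 2.23 for inflammatory genes.

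The second comparison asked how Sting-/- hearts differed from WT hearts when both had received doxorubicin. Genes of contraction and mitochondrial metabolism were far lower in the Sting-/- libraries, and genes of matrix, endothelium and mesothelium far higher. Inflammatory, neutrophil and some interferon-stimulated genes were lower. With an estimated correlation in camera, the lists of contraction and of the tricarboxylic acid cycle passed. The lists of oxidative phosphorylation, fatty acid oxidation, matrix, endothelium, mesothelium, inflammation, neutrophils and interferon response did not. Of the 12485 genes tested, 6760 were higher and 3708 lower (limma, adjusted p of 0.05), and 2174 and 1254 of these changed by at least 2-fold. The ranges of both groups did not overlap for 10584 genes (84.8%, where chance gives 10%). The largest rises were those of Comp, from 0.590 ± 0.151 to 98.8 ± 2.96 FPKM (log2 fold change 5.98, SE 0.089, limma adjusted p = 7.66e-14), C1qtnf3 (5.83), Fmod (5.69), Col11a1 (5.21), Eln (5.20), Sfrp2 (5.09), Ptn (5.04) and Mdk (4.98). The largest falls were those of Ly6c2 (-4.96), Sting1 (0.06, 0 and 0 FPKM in the Sting-/- libraries), Nmrk2 (-4.18), Pdk4 (-4.12), Arg1 (-3.93), Chil3 (-3.84), Fbp2 (-3.84) and Dbp (-3.78). Ly6c2 has a close paralog, Ly6c1, which was chosen after its values were seen and went from 252.6 ± 37.8 to 1091 ± 29.3 FPKM, so how reads were divided between them is uncertain.

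The cardiomyocyte markers were lower in Sting-/- DOX in 16 of 16 cases, with a median log2 fold change of -2.05 (camera adjusted p = 3.11e-12; adjusted p = 0.029 with an estimated correlation). Mb, which encodes myoglobin, was at 9578 ± 106 FPKM in WT DOX and 1761 ± 36.3 FPKM in Sting-/- DOX. Pln, which encodes phospholamban, was at 2520 ± 40.7 and 293.7 ± 5.46 FPKM (SD, n = 3 each). Beside this fall, the tricarboxylic acid cycle list fell in 18 of 18 cases (median -2.45, camera adjusted p = 2.69e-14; adjusted p = 0.0218 with an estimated correlation). The sarcomere list, which shares several members with the cardiomyocyte markers, fell in 18 of 18 (median -2.10, camera adjusted p = 2.9e-13; adjusted p = 0.029 with an estimated correlation) and glycolysis in 19 of 20 (median -1.06, camera adjusted p = 3.18e-11; adjusted p = 0.0265 with an estimated correlation). Oxidative phosphorylation genes fell in 51 of 51 cases (median -1.82, camera adjusted p = 4.12e-26; adjusted p = 0.0666 with an estimated correlation) and fatty acid oxidation genes in 27 of 30 (median -2.41, camera adjusted p = 1.19e-14; adjusted p = 0.0918 with an estimated correlation). Ppargc1a, a regulator of mitochondrial biogenesis, went from 16.1 ± 0.698 to 1.31 ± 0.093 FPKM. Genes of calcium handling fell in 16 of 18 cases (camera adjusted p = 8.43e-09; adjusted p = 0.0746 with an estimated correlation) and those of mitochondrial biogenesis and dynamics in 19 of 24 (camera adjusted p = 5.09e-06; adjusted p = 0.0265 with an estimated correlation). Cd36 was 0.16 and Cpt1a 0.25 higher on the log2 scale, but Cd36 was lower with median-ratio scaling (-0.18). The call of Cpt1a was lost with median-ratio scaling (-0.085) and quantile normalization (0.091).

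Endothelial markers were higher in 23 of 23 cases, with a median of 2.03 (camera adjusted p = 2.86e-08; adjusted p = 0.0921 with an estimated correlation). Tie1, an endothelial receptor, went from 23.1 ± 0.488 to 134.9 ± 6.24 FPKM. Matrix genes were higher in 25 of 27 cases (median 2.39, camera adjusted p = 7.82e-08; adjusted p = 0.168 with an estimated correlation). Col1a1 was at 126.0 ± 0.942 FPKM in WT DOX and 1988 ± 62.4 FPKM in Sting-/- DOX, while Timp1 fell by 0.34 on the log2 scale, a call lost with quantile normalization (-0.001), TPM scaling with or without haemoglobin genes (-0.27 and -0.25) and a pseudocount of 0.1 (-0.34). Fibroblast markers were higher in 13 of 14 cases (median 1.49, camera adjusted p = 2.3e-04; adjusted p = 0.0918 with an estimated correlation) and epicardial and mesothelial markers in 9 of 9 (median 2.21, camera adjusted p = 0.00249; adjusted p = 0.269 with an estimated correlation). The erythroid list rose in 7 of 8 cases (median 2.42, camera adjusted p = 0.047; adjusted p = 0.445 with an estimated correlation), a call that 6 other alternatives also lost. The list mean was 1.17 with TPM scaling without haemoglobin genes and 1.74 to 1.88 with the other 5, against 1.76 in the main fit. The value of 1.17 is that of a smaller list, because this setting removes its globin genes. Its alpha globin genes are near-identical copies whose separate values are uncertain. The smooth muscle list had 11 of 13 members higher and 1 lower and a mean of 1.16 and did not pass the test (camera adjusted p = 0.0525). It passed without saline library 1 (mean 1.16), WT DOX library 1 (1.13) or 2 (1.19) or Sting-/- DOX library 3 (1.18) and with median-ratio scaling (0.84), quantile normalization (1.05), sample weights (1.15), a pseudocount of 0.1 (1.23) or no filter on low values (1.16).

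**Figure D3:**
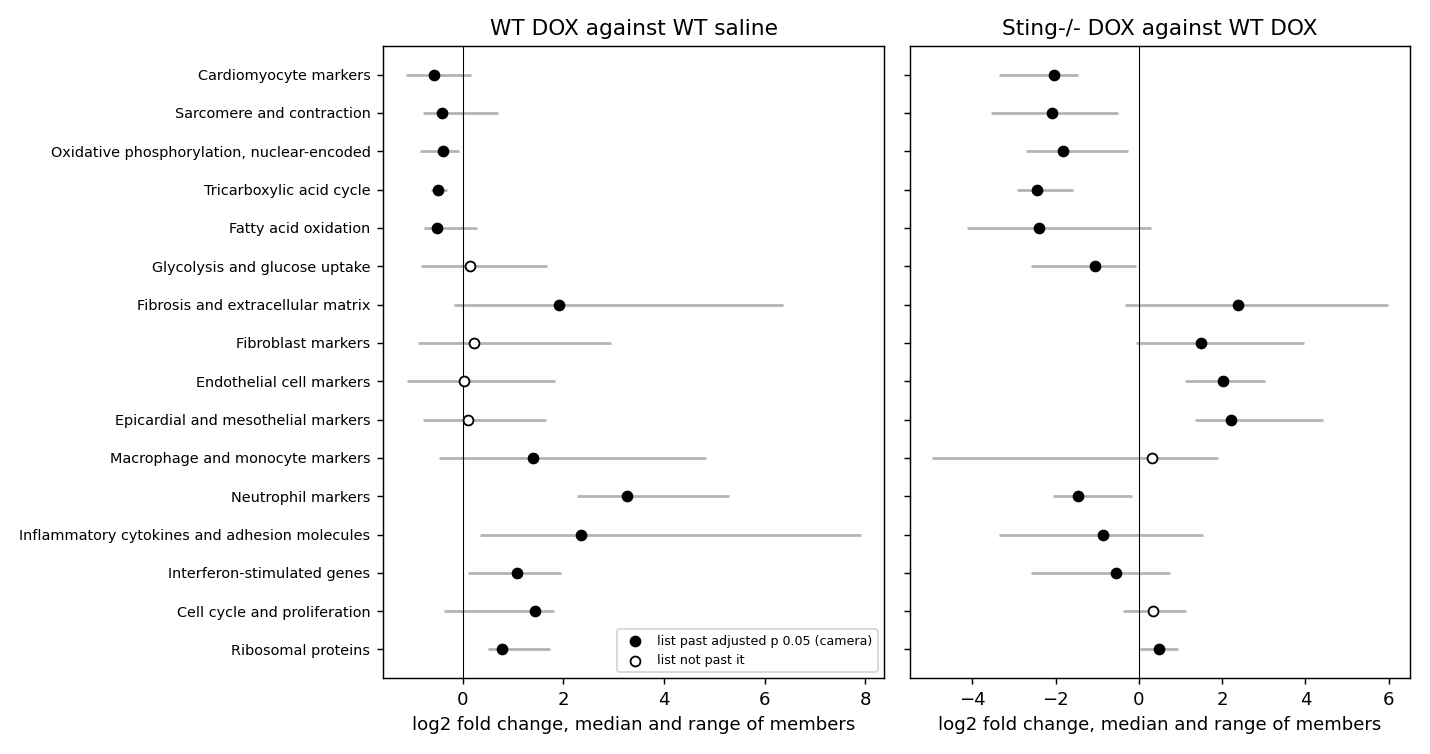
Points are the median log2 fold change of the tested members of 16 gene lists (y axis) and lines their range, on the log2(FPKM + 1) scale (x axis), for WT DOX against WT saline and Sting-/- DOX against WT DOX; filled points passed camera with a preset correlation. Cardiomyocyte markers lie at -0.58 and -2.05, and endothelial markers at 0.03 and 2.03.

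Inflammatory genes were lower in Sting-/- DOX in 14 of 22 cases and higher in 6, with a median of -0.86 (camera adjusted p = 0.00775; adjusted p = 0.0921 with an estimated correlation). This call was lost with median-ratio scaling (mean -1.0) and with a mean of at least 5 FPKM (mean -0.85), although the main fit had a smaller mean of -0.72. Ccl2 was at 131.6 ± 12.3 FPKM in WT DOX and 11.8 ± 0.178 FPKM in Sting-/- DOX, while Cx3cl1 and Icam1 were higher. Vcam1 was at 24.93, 24.28 and 23.26 FPKM in the Sting-/- DOX libraries, above every WT DOX library, of which the highest was at 16.72 FPKM. Neutrophil markers were lower in 6 of 7 cases (median -1.46, camera adjusted p = 0.00151; adjusted p = 0.117 with an estimated correlation), a call lost with a mean of at least 5 FPKM, where the mean was -1.43 against -1.41 in the main fit. Macrophage and monocyte markers went both ways, with 11 of 19 higher and 6 lower (median 0.32, camera adjusted p = 0.735). Interferon-stimulated genes were lower in 23 of 36 cases and higher in 4, with a median of -0.56 (camera adjusted p = 3.05e-04; adjusted p = 0.627 with an estimated correlation). Ifit3 went from 124.8 ± 43.7 to 35.9 ± 1.17 FPKM and Irf7 from 214.3 ± 28.6 to 94.4 ± 3.66 FPKM, while Oas2 and Rsad2 were higher. The cGAS-STING list, with 6 of 16 higher and 8 lower, did not pass the test (camera adjusted p = 0.219). Irf3 rose from 25.4 ± 0.991 to 60.5 ± 3.81 FPKM. Cgas had a log2 fold change of 0.07 (limma adjusted p = 0.572), which passed as lower with quantile normalization (-0.275). Tbk1 rose by 0.18, which was -0.14 with median-ratio scaling and -0.079 with quantile normalization.

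Cd38 was higher in Sting-/- DOX, at 27.0 ± 1.15 FPKM against 8.74 ± 0.386 FPKM in WT DOX (SD, n = 3 each; log2 fold change 1.52, SE 0.062, limma adjusted p = 2.91e-10; higher in 3 of 3 libraries). Of the 23 endothelial markers, which had log2 fold changes of 1.11 to 3.02, 20 rose by more than Cd38. Nmrk2 fell from 289.2 ± 40.0 to 14.9 ± 0.619 FPKM, Nampt from 58.8 ± 9.59 to 18.4 ± 0.386 FPKM, Bst1 from 9.22 ± 0.329 to 4.06 ± 0.739 FPKM, Parp1 from 18.5 ± 0.809 to 9.82 ± 0.261 FPKM and Nnt from 78.5 ± 2.71 to 14.1 ± 0.0929 FPKM. Neither NAD list passed the test: NAD consumption, with 8 of 18 higher and 5 lower, had a median of -0.05 and a mean of 0.08 (camera adjusted p = 0.642). NAD synthesis, with 8 of 15 higher and 6 lower, had a median of 0.30 and a mean of -0.35 (camera adjusted p = 0.474). Nppb fell from 1277 ± 35.4 to 297.9 ± 15.9 FPKM and Myh7 from 123.7 ± 25.2 to 51.1 ± 2.36 FPKM, whereas Cdkn1a rose from 53.6 ± 4.72 to 78.6 ± 4.32 FPKM. Nppa rose from 2798 ± 174 to 3674 ± 64.1 FPKM, a call lost with median-ratio scaling (log2 fold change 0.051). Beside the fall of the cardiomyocyte markers (median -2.05), the cardiac stress list fell in 9 of 13 cases and rose in 4 (median -1.24, camera adjusted p = 0.00174; adjusted p = 0.192 with an estimated correlation). The atrial cardiomyocyte markers had 6 of 8 higher and 1 lower and a median of 0.73, and did not pass the test (camera adjusted p = 0.273).

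**Figure D4:**
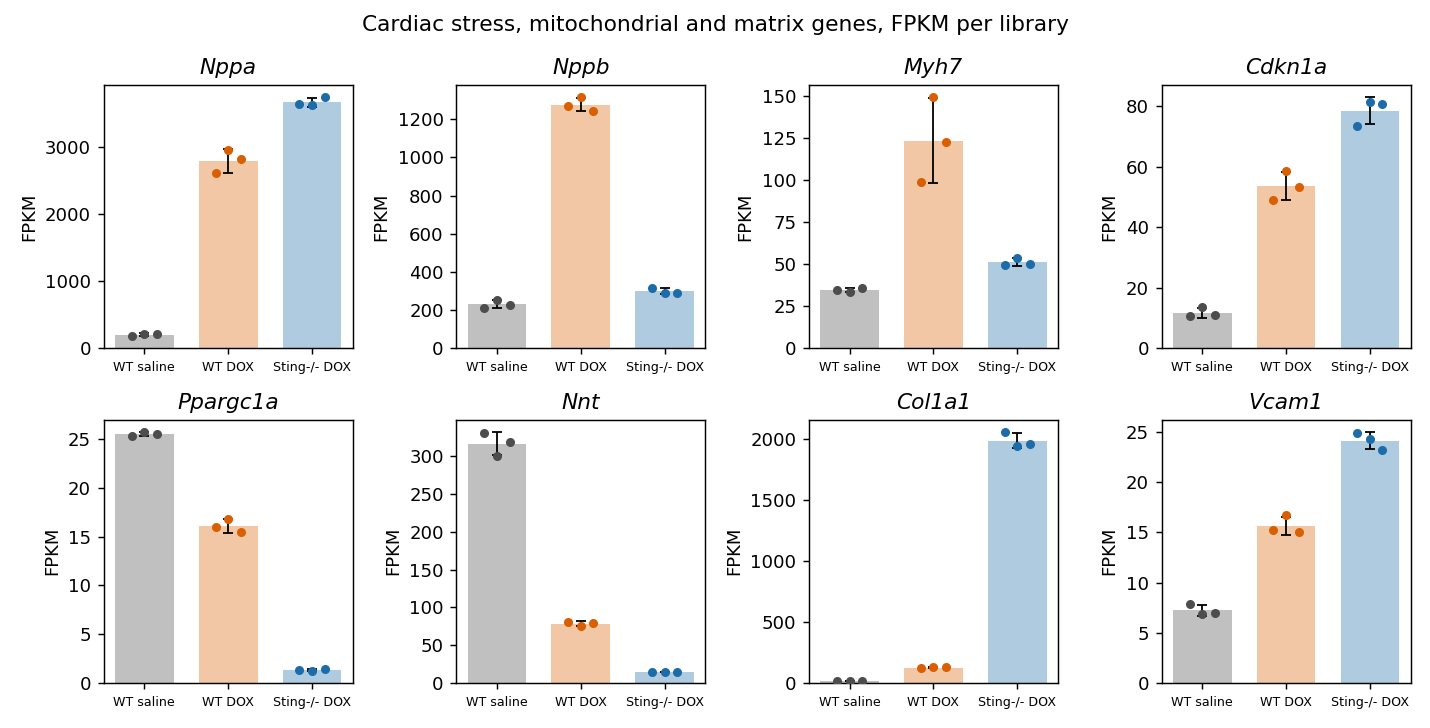
Bars are group means of FPKM (y axis), error bars are SD, and points are the 3 libraries of each group for 8 genes of cardiac stress, mitochondria and matrix. Nppb is highest in WT DOX, at 1277 FPKM, while Col1a1 is highest in Sting-/- DOX, and Ppargc1a and Nnt are lowest there.

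Lists of stress and timing also differed between Sting-/- DOX and WT DOX. The labels do not give the time of day at which hearts were taken, which clock genes follow. The clock list was lower in 13 of 17 cases and higher in 4 (camera adjusted p = 0.00162; adjusted p = 0.179 with an estimated correlation), with Dbp at 51.3 ± 2.18 FPKM in WT DOX and 2.81 ± 0.361 FPKM in Sting-/- DOX, and Arntl at 1.91 ± 0.0907 and 18.1 ± 0.980 FPKM. Glucocorticoid-responsive and fasting genes were lower in 11 of 16 cases (camera adjusted p = 0.00162; adjusted p = 0.0666 with an estimated correlation), and antioxidant genes in 16 of 25 (camera adjusted p = 0.0017; adjusted p = 0.116 with an estimated correlation). Ribosomal protein genes were higher in 25 of 26 cases (median 0.48, camera adjusted p = 3.5e-04; adjusted p = 0.116 with an estimated correlation), a call lost with median-ratio scaling (mean 0.14). The list of strain and substrain genes, of which Nnt is a member, was lower in 6 of 8 cases (camera adjusted p = 0.00775; adjusted p = 0.0918 with an estimated correlation). In all, 22 of 41 lists passed, and 5 passed with an estimated correlation. Of the genes called, 64.6% were higher with FPKM as deposited, 51.4% with quantile normalization and 46.7% with median-ratio scaling, which moved the median of all genes from 0.249 to -0.049. Relative to the median with FPKM as deposited, cardiomyocyte markers were at -2.30 and endothelial markers at 1.78.

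Genes that doxorubicin changed in WT hearts were then followed into the Sting-/- hearts. In all, 1215 genes were higher in WT DOX than in saline and lower in Sting-/- DOX than in WT DOX, where independent lists would share 1678. A further 922 were lower and then higher, where independent lists would share 1451. With FPKM as deposited, more genes moved the same way in both comparisons: 3520 rose in both (3060 for independent lists) and 1463 fell in both (796). These counts depend on the scaling. The total of opposite changes, 2137 in the main fit, was 2688 with median-ratio scaling and 2904 with quantile normalization. It was 1633 with a mean of at least 5 FPKM, where fewer genes are tested. No alternative is given here for the counts of genes that moved the same way. The genes with the largest opposite changes were Arg1, Ly6c2, Chil3, Nmrk2, Ccl2, Slfn4, Lcn2 and Ccl7. Arg1, which encodes arginase, was at 0.183 ± 0.214 FPKM in saline, 159.4 ± 13.2 FPKM in WT DOX and 9.53 ± 0.753 FPKM in Sting-/- DOX, and Ccl7 at 6.32 ± 0.838, 147.3 ± 16.6 and 22.2 ± 2.67 FPKM. At 2-fold in both comparisons, 134 genes rose and then fell (117 for independent lists) and 11 fell and then rose (15), while 234 rose in both (202) and 31 fell in both (9).

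Both comparisons use the WT DOX libraries, with opposite signs, so chance alone makes changes look opposite. In 100 simulations of unchanged groups, fold changes had a correlation across genes of -0.499 and a covariance of -0.0046. No gene was called in opposite directions in them. With nothing changed hardly any gene is called at all, so that was likely beforehand. It gives no expected number of opposite calls among genes that do change. The observed correlation was 0.107 and the observed covariance 0.0682, a difference of 0.0728 from the simulated covariance. The 3 WT DOX libraries could not be divided into parts of at least 2, so part of the opposite changes may come from sharing them.

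The third comparison set Sting-/- DOX hearts beside WT saline hearts, which differ in genotype and treatment together. Here 7869 genes were higher and 3228 lower (limma, adjusted p of 0.05), of which 3830 and 1400 changed by at least 2-fold, and the ranges of both groups did not overlap for 11140 genes (89.2%, where chance gives 10%). The largest rises were those of Cthrc1 (7.99), Lox (7.08), Sprr1a (6.94), Col1a1 (6.91), Sfrp2 (6.87), Spp1 (6.65), Saa3 (6.09) and Ltbp2 (6.08) on the log2 scale. The largest falls were those of Dbp (-4.61), Mylk4 (-4.49), Fbp2 (-4.41), Nnt (-4.39), Dgat2 (-4.13), Pdk4 (-4.07), Ckmt2 (-4.06) and Atp2a2 (-3.94). Cardiomyocyte markers were lower in 16 of 16 cases (median -2.77, camera adjusted p = 1.19e-13; adjusted p = 0.0273 with an estimated correlation), and matrix genes were higher in 27 of 27 (median 4.05, camera adjusted p = 2.21e-08; adjusted p = 0.139 with an estimated correlation). The atrial cardiomyocyte markers were higher in 6 of 8 cases and lower in 1, with a median of 3.42, and did not pass the test (camera adjusted p = 0.212). Endothelial markers were higher in 23 of 23 (median 2.05, camera adjusted p = 6.38e-06; adjusted p = 0.132 with an estimated correlation). Of the 41 lists, 20 passed, and 4 passed with an estimated correlation. Of the genes called, 70.9% were higher with FPKM as deposited, 51.3% with quantile normalization and 49.0% with median-ratio scaling, which moved the median of all genes from 0.494 to -0.016.

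Some genes raised by doxorubicin in WT hearts were nearer to the saline level in Sting-/- hearts. Irf7 was at 88.4 ± 3.42 FPKM in saline and 94.4 ± 3.66 FPKM in Sting-/- DOX (log2 fold change 0.09, limma adjusted p = 0.272), although it was lower with median-ratio scaling (-0.496). Isg15 had a log2 fold change of 0.37 (limma adjusted p = 0.0683), which passed the test without saline library 2 (0.53), WT DOX library 1 or 2 (0.365) or Sting-/- DOX library 1 (0.48). It also passed with a replicate block or only the 2 groups compared (0.365), sample weights (0.41) and TPM scaling without haemoglobin genes (0.42). Nppb was 0.37 and Nmrk2 0.52 higher than in saline on the log2 scale, but Nppb was lower than in saline with median-ratio scaling (-0.22). The call of Nmrk2 was lost with median-ratio scaling (-0.029) and quantile normalization (0.066). The cardiomyocyte markers had a median of -2.77 in this comparison, and Nppb and Nmrk2 did not fall with them. Their nearness to saline therefore need not be a return to the saline level within cardiomyocytes, which was not measured. The interferon list, with 18 of 36 higher and 9 lower (7 lower adjusted over the list alone), had a median of 0.44 and did not pass the test (camera adjusted p = 0.884). Inflammatory genes stayed higher than in saline in 21 of 22 cases (median 1.64, camera adjusted p = 0.00233; adjusted p = 0.0723 with an estimated correlation).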

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

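Counts of genes changed by at least 2-fold, with their alternatives, were chosen after the data were seen; the other alternatives were chosen before. Of 10317 alternative values for 494 named gene results, 10211 kept their direction and side of the threshold, 68 lost the call, 17 gained one and 21 reversed. Of 2694 values for list results, 2593 kept both, 66 lost the call, 35 gained one and none reversed. Depth was known only approximately and limits genes near 1 FPKM.

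Scaling and the filter on low values moved counts of genes, and an estimated correlation in camera moved counts of lists by more; the causes were not tested. In WT DOX against saline, 3582 genes were higher and 5109 lower with median-ratio scaling, and 3461 and 5363 with quantile normalization. At 2-fold, 765 were higher with quantile normalization, and the 85 genes lower became 228 with median-ratio scaling, 211 with quantile normalization, 129 with TPM scaling, 130 with TPM scaling without haemoglobin genes, 164 with a pseudocount of 0.1 and 56 with a mean of at least 5 FPKM, where fewer genes are tested. In Sting-/- DOX against WT DOX, 1283 were at least 2-fold higher with median-ratio scaling. In Sting-/- DOX against saline, 5493 and 5205 were lower with median-ratio scaling and quantile normalization, 2067 and 2194 at least 2-fold higher, and 2312 and 2122 at least 2-fold lower. At a mean of at least 5 FPKM, 88 genes rose and then fell by 2-fold. With an estimated correlation in camera, 7, 5 and 4 lists passed in the 3 comparisons, against 24, 22 and 20.

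Reversed log2 fold changes with median-ratio scaling were, in WT DOX against saline, Irf3 (-0.035), Parp1 (-0.11) and Nkx2-5 (-0.091); in Sting-/- DOX against WT DOX, Tbk1 (-0.14), Cd36 (-0.18), Cpt1a (-0.085) and Uty (-0.10); and in Sting-/- DOX against saline, Tbk1 (-0.095), Irf7 (-0.50), Nmrk2 (-0.029), Nppb (-0.22), Myh7 (-0.032), Cpt1a (-0.04) and Eif2s3y (-0.14). With quantile normalization they were Parp1 (-0.065), Actc1 (0.13) and Nkx2-5 (-0.028) in WT DOX against saline, Cgas (-0.28), Tbk1 (-0.079) and Uty (-0.063) in Sting-/- DOX against WT DOX, and Tbk1 (-0.038) in Sting-/- DOX against saline. The cause was not tested.

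Libraries with the same number deviated together little across all genes (correlation -0.032 to 0.104, against -0.066 to 0.035 for other numbers in other groups). The highest value was that of saline and WT DOX library 2. Isg15 and Irf7 were lowest in library 1 and highest in library 2 in each group, while Ifit3 and Cxcl10 did not keep this order. Pairing by number is therefore not excluded. With a replicate block, 5607 genes were higher and 2640 lower in WT DOX against saline, 6749 and 3700 in Sting-/- DOX against WT DOX, and 7879 and 3225 in Sting-/- DOX against saline. Leaving out each library gave 5285 to 5608 higher and 2427 to 2703 lower in WT DOX against saline, 6516 to 6802 and 3556 to 3717 in Sting-/- DOX against WT DOX, and 7664 to 7886 and 3130 to 3222 in Sting-/- DOX against saline.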

Other observations

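The tests of cardiomyocyte share, scaling and Nnt, and the counts of other splits, were chosen after the results were seen, except that the comparison of Ide and Fgfbp3 with their flanking genes was written before the flanking genes were looked at, though the values of Ide and Fgfbp3 had been seen. The genes in the next paragraph were also chosen after their values were seen.

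Acan and Col2a1, matrix genes of cartilage, were near 0 in both WT groups but not in Sting-/- DOX. They were at 4.86 ± 0.202 and 3.91 ± 0.225 FPKM there (SD, n = 3), against 0.01 ± 0 and 0.0267 ± 0.0306 FPKM in WT DOX, and Sox9 was at 11 ± 0.562 FPKM against 1.23 ± 0.192 FPKM. The imprinted genes Igf2 and Mest were at 74.2 ± 3.43 and 51.8 ± 1.72 FPKM, against 13.1 ± 0.655 and 9.28 ± 0.745 FPKM in WT DOX and 8.83 ± 0.685 and 4.72 ± 0.243 FPKM in saline. Among genes of macrophages, Trem2 was at 2.43 ± 0.662, 31.3 ± 1.60 and 120.5 ± 5.72 FPKM in saline, WT DOX and Sting-/- DOX, while Ccr2 was at 1.2 ± 0.0815, 30.6 ± 1.06 and 17.7 ± 0.913 FPKM.

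Differences between libraries of a group were 1.22 to 1.63 times the sampling noise at the estimated depth. The depth is approximate, and the longest transcript of each gene was used, which can raise this ratio. It does not decide whether the libraries of a group came from separate animals, so the p-values may rest on technical spread.

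Cardiomyocyte genes were lower and genes of other cell types higher in Sting-/- DOX than in WT DOX. A few abundant genes taking a different part of the FPKM total is argued against, because the cardiomyocyte median stayed at -2.39 with median-ratio scaling (quartiles -2.99 and -2.26). A lower share of cardiomyocytes as the whole cause is argued against, because other cell types did not rise alike. Endothelial markers were higher in 23 of 23 cases, macrophage markers higher in 11 of 19 and lower in 6, and the endothelial median exceeded the macrophage median by 1.71. Permutation of genes gave a two-sided p = 2e-05, the smallest that the draws can give. It treats genes as independent, while members of these lists vary together (estimated correlations 0.18 and 0.061), so this p-value overstates the evidence. A lower share together with changes in other cells, a different part of the heart sampled, and an effect of the genotype stay open and were not tested as causes. Of the atrial cardiomyocyte markers, which bear on the part sampled, 6 of 8 were higher and 1 lower (median 0.73, camera adjusted p = 0.273). The cardiomyocyte markers fell in 16 of 16 cases (median -2.05), so these lists moved apart. They also did so in WT DOX against saline, so this is not particular to the Sting-/- libraries. There the atrial markers had 5 of 8 higher and 3 lower (median 1.73) and the cardiomyocyte markers 1 of 16 higher and 13 lower (median -0.58). Camera sets a list against all genes and not against another list, so its p-value does not bear on a difference between these lists. No test compared the lists with each other, and the part sampled stays undecided.

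Nnt was lower in WT DOX than in saline, with a log2 fold change of -2.0. Nnt fell by more than all members of the mitochondrial and cardiomyocyte lists compared with it, which lay between -1.13 and 0.16. It was compared with them after its fall was seen to be 1 of the 8 largest, so a place below them was likely beforehand. This therefore does not decide whether less mitochondrial and cardiomyocyte RNA was the whole cause. A substrain difference was looked for in Ide and Fgfbp3, which share a copy-number variant among substocks of C57BL/6J and had FPKM ratios of 2.17 and 2.55. Only 6 of the 10 genes that flank the pair had lower ratios than both, short of the 8 set beforehand, and Ankrd1, Kif11, Myof and Cep55 rose by more than the pair. That bound took the flanking genes to be steady under the drug, which was wrong: Kif11 belongs to the cell cycle list (27 of 28 higher) and Ankrd1 to the cardiac stress list (9 of 13 higher), though Myof and Cep55 are in no fixed list. The 3 genes between the pair, Btaf1, Cpeb3 and Marchf5, had ratios of 1.725, 0.468 and 1.08, which a gain of the whole stretch alone would not give, but the drug can move them too and the files do not show which genes the variant holds. The test therefore does not decide, and a substrain difference stays open. A difference at Nnt alone and an effect of doxorubicin were not tested.

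For each comparison, the 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 8331 genes in WT DOX against saline, 10468 in Sting-/- DOX against WT DOX and 11097 in Sting-/- DOX against saline. In each case 1 split gave as many, the real one, while the highest of the others gave 0. Each other split mixes libraries of both groups, so a difference between the groups becomes spread within the mixed ones. Few or no calls were therefore likely there beforehand, and no conclusion is drawn from these counts.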
